A study of Mus musculus with 10 samples.

How the data were processed

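Immune cells sorted from pooled subcutaneous allografts were read with the 10x Genomics 5' V(D)J kit, as expression libraries of 5 conditions (KP vehicle, KPL vehicle, KPL BGB324, KPL anti-PD-1 and KPL combination) and as TCR libraries, of which 4 were analysed. The deposited expression values are raw UMI counts per gene and cell barcode for 32285 genes, per the file headers written by Cell Ranger 3.1.0. All expression libraries list the same genes, but how each was aligned is not documented further, so ratios of genes that stand out in 1 library in all classes are uncertain. The labels name mm10 (GRCm38) and Seurat 3.2.1. The deposited TCR values are counts of UMIs and reads per assembled contig of barcodes called as cells. A second copy of each expression matrix was identical and was not used. A TCR library of KPL BGB324 is listed too, but its contigs were not among the files used here. How the 10 KPL allografts were divided over the 4 KPL samples is not given, so the number of tumours behind each KPL library is unknown.

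Cells with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept. In each library the cells with the highest Scrublet scores were removed at a rate of 0.8% per 1000 cells, which took out 199, 173, 131, 284 and 275 cells in the library order above and left 4783, 4471, 3923, 5675 and 5591. The libraries were clustered together without batch integration, after scaling to 10000 UMIs per cell and taking logs, on 2000 variable genes without TCR and immunoglobulin segment genes, with 30 principal components, 15 neighbours and Leiden resolution 1. The tools were Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Random steps used seed 1.

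Clusters were named from 23 marker sets, and a set could name a cluster only with at least 3 of its markers in at least 10% of the cells, a limit added after the data were seen. One cluster of 86 cells stayed unnamed. T cells of all T cell clusters were gated by markers: CD8 T cells had a Cd8a or Cd8b1 UMI and no Cd4 UMI, CD4 T cells the reverse, and CD4 T cells with a Foxp3 UMI were called regulatory and the others conventional. T cells with no UMI of these genes were 53.7%, 39.5%, 16.7%, 36.6% and 28.8% of T cells and were left in the denominator. The regulatory gate held 142, 310, 89, 447 and 140 cells, fewer than the cluster led by Foxp3, Ikzf2 and Il2ra (353, 646, 196, 1101 and 423). Conventional CD4 T cells may thus include regulatory T cells whose Foxp3 was not read. How many was not counted. Non-T immune classes were given as shares of non-T immune cells because CD3+ and CD3- cells were sorted apart and then mixed. Macrophage and monocyte clusters were combined for shares and sums and also given apart, the latter chosen after the data were seen. Shares have exact Clopper-Pearson 95% intervals.

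Shares of CD8 T cells with a UMI of a gene were taken after drawing 1500 UMIs from each cell without replacement, leaving out shallower cells. Neutrophils thinned in the same way served as background. A share of 0 is given with the upper end of its exact interval.

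UMIs were summed per library and class where both libraries of a pair held at least 50 cells of it. Sums were scaled to the class total as CPM, and log2 ratios of CPM have exact conditional binomial 95% intervals. A gene with 0 counts on one side is given as at least N-fold against a floor of 3 counts in that library. In 10 of 38 class and pair combinations the median gene had a log2 ratio more than 0.1 away from 0, and the report gives these. Tested on 20 sets of simulated data with 200 changed genes, the interval held the true ratio for 95.7% of unchanged genes in CD8 T cells, combination against KPL vehicle, and lay on the true side of 0 for 54.6% of genes changed 1.25-fold, 84.7% of those changed 1.5-fold and 99.8% of those changed 2-fold. The simulated sums had counting error only, the error that the interval assumes. They held no variation between cells or tumours, so these rates do not cover it.

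Of 22 gene lists written before the data were examined, the report gives TCF1 progenitor, exhaustion, cytotoxic, type I interferon, interferon gamma, cell cycle, MHC class I, hypoxia and glycolysis, oxidative phosphorylation, dissociation stress, neutrophil, fibroblast and tumour, and erythrocyte genes in CD8 T cells. In macrophages and monocytes it gives both interferon lists, interferon induction, MHC class II, suppressive, inflammatory, complement and lipid, and chemokine genes. It also gives the TAM list there, of the receptors Axl, Mertk and Tyro3 and the ligands Gas6 and Pros1. Maturation genes were read in dendritic cells and regulatory T cell genes in regulatory T cells. Which list is given in which class was narrowed after the data were seen. A list's value is the median log2 ratio of its genes with at least 20 UMIs over both libraries, and at least 3 such genes were needed. Its percentile is among 10000 random lists of the same size, each gene drawn from the 100 genes nearest in expression. These percentiles describe 2 libraries and test nothing about conditions.

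Single genes were named by a rule fixed before the data were examined. Genes with at least 100 UMIs over the 2 libraries were ranked by the interval bound nearest 0, without TCR and immunoglobulin segments, mitochondrial, ribosomal protein and haemoglobin genes, unnamed transcripts, sex-linked markers, Malat1 and Neat1. For KPL vehicle against KP vehicle and for the combination against KPL vehicle, the ranking named 6 genes each way in CD8 T cells, 4 in macrophages and monocytes, and 3 in dendritic cells where compared, and for the other pairs 3, 2 and 2. Up to 4 genes of each list were named by their bounds, and Tcf7, Pdcd1, Slamf6, Havcr2, Gzmb, Ifng, Axl, Mertk, Foxp3, Arg1, Isg15, Ifit3, Cxcl9 and Cxcl10 always could be. Some genes that the rule names are not reported here. A further ranking, added after the data were seen, leaves out genes under 25% of their CPM in the highest class of the library and genes that differ 2-fold or more in the same direction in every class.

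Clonotypes are those of the contig tables. Libraries of 322, 789, 927 and 1117 barcodes were drawn down to 322 barcodes 1000 times, and the share of barcodes in clonotypes of 2 or more is the mean over draws with its 95% range. Of TCR barcodes, 98.0% to 99.6% were found in the expression library of their own condition and at most 1.55% in any other.

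The 6 pairs of libraries were compared without tests, since each condition has 1 library, and 4 pairs share KPL vehicle, so their ratios are not independent. Alternatives fixed before the data were examined were at least 1000 UMIs per cell, at most 5% mitochondrial UMIs, no doublet removal or a factor of 2 on its rate, Leiden resolutions 0.5 and 2, subsets from T cell sub-clusters or after thinning, thinning to 1000 or 2500 UMIs or none, at least 2 Tcf7 UMIs, CD8 T cells with a TRB contig or with both CD8 chains, other scalings, the mean of each cell's CPM, list floors of 100 and 1 UMI, list means, clonotypes by TRB nucleotide sequence, T cell barcodes only, no drawing, and at least 3 UMIs on the TRB contig. Added after the data were seen were Tcf7-positive CD8 T cells over all T cells, Tcf7 with Pdcd1 over all T cells, Tcf7 among Pdcd1-positive CD8 T cells, and list medians over genes with at least 25% of the CPM of the highest class.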

Results

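Single-cell RNA and T cell receptor (TCR) sequences were read from immune cells of subcutaneous tumours grown in C57BL/6 mice from 2 lung cancer lines. KP cells lack Trp53, and KPL cells also lack Stk11, the gene of the kinase LKB1. KP tumours were given vehicle with IgG. KPL tumours were given vehicle with IgG, BGB324 (an inhibitor of the receptor tyrosine kinase AXL), an antibody against PD-1, or BGB324 and the antibody in combination. The allografts, 10 of KP and 10 of KPL, were taken 14 days after implantation at about 200 mm3. Tumours of a condition were pooled, and live CD45+ CD3- and CD45+ CD3+ cells were sorted and mixed 1:1. Each of the 5 conditions had 1 expression library, and the TCR libraries of 4 conditions were used.

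The KP vehicle library held 5323 cell barcodes with 19095175 unique molecules (UMIs), and the KPL vehicle library held 5422 with 46058362. KPL BGB324 had 4508 barcodes and 24169472 UMIs, KPL anti-PD-1 6742 and 43725586, and the KPL combination 6205 and 23365950. Median UMIs per barcode were 2117, 4003, 3404.5, 3200 and 2578 in the same order. No condition had a replicate library, so no difference between conditions could be tested, and the exact 95% intervals given here cover counting error only. Expression is compared as log2 ratios of CPM (UMIs of a gene scaled to all UMIs of the class), the first-named library over the second. A gene list is given by the median ratio of its genes, with its percentile among medians of random lists of like expression.

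After filtering, 24443 cells formed 20 clusters, of which 1 (86 cells) had no clear identity. Neutrophils filled 5 clusters, led among others by Mmp9 and Siglecf, by S100a8 and S100a9, or by the interferon-response genes Rsad2, Slfn4, Ifit1 and Isg15 (cluster 6). Macrophages formed cluster 3, led by Apoe, C1qc, C1qb, Pf4, C1qa and Ms4a7, and monocytes formed cluster 4, led by Lyz2, Chil3 and Ms4a4c. Dendritic cells (Plet1, Cd209a, Mgl2), NK cells (Gzma, Klrb1c) and epithelial or tumour cells (Krt8, Krt18, Wfdc2) had 1 cluster each, and B cells a cluster of 44 cells, too few to compare. T cells fell into 8 clusters, led by CD8 genes (cluster 8), Foxp3, Ikzf2 and Il2ra (cluster 15), Cd163l1 and Trdc (cluster 11), the interferon-response genes Ifi208, Ifi206 and Ifit1bl1 (cluster 17), dividing-cell genes such as Top2a (cluster 18), or Klra7, Cd7 and Ccl5 (cluster 9). No cluster was named innate lymphoid here. At Leiden resolution 2 one was, led by Il13, Calca and Il1rl1 among others. It held 89 KP vehicle, 19 KPL vehicle, 19 BGB324, 158 anti-PD-1 and 40 combination cells. A T cell sub-cluster led by Calca and Il13 among others held 35, 4, 3, 82 and 7, so the T cell denominators may include such cells unevenly. The cluster with the most T cells differed between libraries: cluster 9 in KP vehicle (26.8%), cluster 15 in KPL vehicle (48.4%) and KPL anti-PD-1 (36.3%), and cluster 8 in KPL BGB324 (51.1%) and the KPL combination (32.9%). Of macrophages and monocytes, cluster 3 held most in KP vehicle (75.5%), KPL vehicle (89.6%) and the combination (58.0%), and cluster 4 held most in BGB324 (90.5%) and anti-PD-1 (52.3%). T cells were 31.8%, 32.3%, 46.4%, 60.0% and 37.1% of immune cells in the order KP vehicle, KPL vehicle, BGB324, anti-PD-1 and combination, and these shares were not compared because sorted cells had been mixed.

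**Figure D1:**
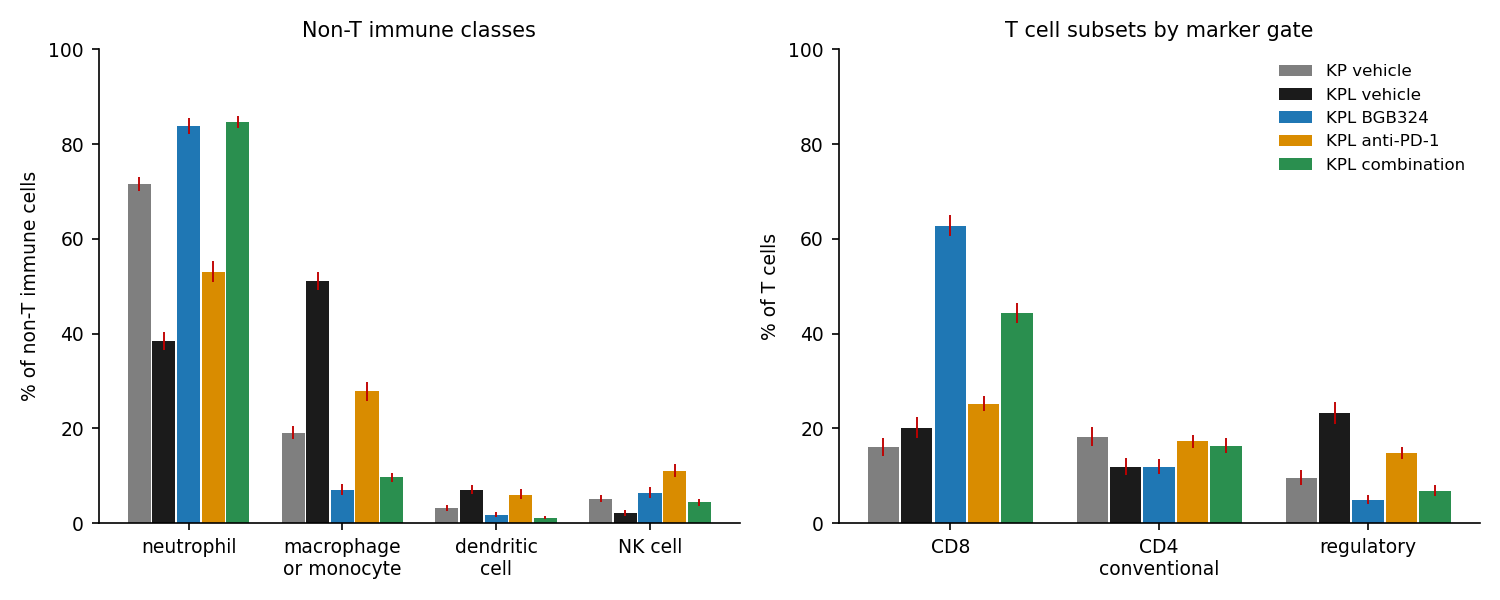
Shares of non-T immune cells (percent, left) and of T cells (percent, right) by library, with exact 95% intervals that cover counting error only. Neutrophils were 38.4% of non-T immune cells in KPL vehicle and 84.6% in the combination, and CD8 T cells were 20.1% and 62.8% of T cells in KPL vehicle and KPL BGB324.

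The first comparison, KPL vehicle against KP vehicle, asks how immune cells of tumours from the line without Stk11 differ. Stk11 itself was read in the epithelial or tumour cluster at 22.6 CPM (19.6 to 25.9) in KPL and 15.1 CPM (10.8 to 20.7) in KP, so the loss was not seen in these counts of 5' ends, which need not show a deletion further along the gene. KPL tumours held a larger share of macrophages and regulatory T cells and a smaller share of neutrophils and NK cells. CD8 T cells of KPL tumours had less Tcf7, Klf2 and Lef1 RNA, more Pdcd1 RNA and far more RNA of cell cycle genes. Most interferon-response genes were lower in KPL CD8 T cells, macrophages and neutrophils.

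Among non-T immune cells, macrophages and monocytes were 19.1% (17.8 to 20.5) in KP and 51.1% (49.3 to 53.0) in KPL, a log2 ratio of 1.42 (1.30 to 1.54). The macrophage cluster alone was 14.4% and 45.8%, while the monocyte cluster was 4.69% and 5.32%. Where the class divides depends on the clustering: without doublet removal the monocyte cluster held 554 KP and 640 KPL vehicle cells, against 150 and 149 here. Neutrophils were 71.6% (70.0 to 73.1) in KP and 38.4% (36.6 to 40.3) in KPL. Dendritic cells were 3.25% and 7.10%, but with at most 5% mitochondrial UMIs only a cluster of migratory mature dendritic cells was left, with 27 KP and 25 KPL vehicle cells. NK cells were 5.10% and 2.10%. Of T cells, regulatory T cells were 9.53% in KP and 23.2% in KPL, a log2 ratio of 1.28 (1.02 to 1.56), or 0.92 when gated after thinning. CD8 T cells were 16.1% (14.3 to 18.1) and 20.1% (18.0 to 22.4), and conventional CD4 T cells 18.3% and 11.8%. In every library the conventional class may include regulatory T cells whose Foxp3 was not read.

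In CD8 T cells, the TCF1 progenitor genes had a median log2 ratio of -0.98, below all of 10000 random lists of like expression, with 3 of 13 genes above 0. Klf2 had -2.41 (-2.67 to -2.16), Lef1 -1.88 (-2.30 to -1.47) and Tcf7 itself -1.80 (-2.11 to -1.50), the last at 59.4 against 208 CPM. The exhaustion genes had a median of 0.54 (percentile 99.8 of the random lists), with Pdcd1 at 1.26 (1.00 to 1.54) and Tnfrsf9 at 1.28 (1.13 to 1.44). The cytotoxic genes had a median of 0.35 (percentile 94.4): Gzmc was 2.24, Ccl5 -0.63 and Gzmb 0.29 (0.15 to 0.44). Every one of the 15 cell cycle genes was higher in KPL, with a median of 1.97, led by Ube2c at 3.34 (2.69 to 4.06), Birc5 at 3.24 (2.54 to 4.04), Cdk1 at 3.09 and Ccnb2 at 3.04. Type I interferon genes had a median of -0.91 and interferon gamma genes of -0.75, both at percentile 0, with Irf1 at -1.32 (-1.61 to -1.04), Gbp4 at -1.12 (-1.54 to -0.70) and Bst2 at -1.09 (-1.43 to -0.76); the type I median was -0.30 over genes with at least 100 UMIs. Hypoxia and glycolysis genes were higher (0.65, percentile 100, with Gapdh at 0.87 and Tpi1 at 1.03). Oxidative phosphorylation genes had a median of 0.35 with 14 of 14 above 0, but this lay within the random lists (percentile 87.8). MHC class I genes were near the random lists (0.07, percentile 41.2). Dissociation stress genes were lower (-0.72, percentile 0; Fos -2.13, Fosb -1.71). The median gene of CD8 T cells had a log2 ratio of 0.10, to which these values compare.

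The CD8 genes with the largest ratios by the ranking fixed beforehand included Bcl2 at -2.64 (-2.97 to -2.31), Ly6c2 at -2.51 (-2.72 to -2.30) and Klf3 at -2.52 (-3.11 to -1.96) among those lower in KPL. Those higher included Mt1 at 2.52 (2.22 to 2.84), Hist1h1b at 3.19 and Hist1h2ap at 2.62. Pde2a (-2.08) and Phf21a (-2.08) were lower by a ranking added later, which leaves out RNA that another class holds in excess and genes shifted in every class. Bcl2, Ly6c2, Lef1 and Pde2a are also among the leading genes of cluster 9, which was 26.8% of T cells in KP and 8.61% in KPL vehicle, so the mix of T cell clusters moved with them. Hist1h2ao had 0 against 102 UMIs, at least 74.5-fold lower, Hypk had -4.44 and Olfr1369-ps1 5.81. Over all cells KPL vehicle alone stood out for these last genes, so their ratios with it are uncertain.

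Macrophages and monocytes of KPL tumours had more RNA of complement and lipid genes (median 0.97, 12 of 12 genes, percentile 100), several of which define the macrophage cluster that held more of them. Ctsd was 1.22 (1.16 to 1.28), and Gpnmb, of the suppressive genes, was 2.30 (2.02 to 2.60), whereas Arg1 was -2.02 (-2.06 to -1.97) and Retnla -1.96 (-2.06 to -1.87). The suppressive genes as a list had a median of -0.37 (percentile 0.34). Axl was 0.86 (0.70 to 1.01), at 216 against 119 CPM, its ligand Gas6 0.81 (0.60 to 1.03) and Mertk 0.04 (-0.17 to 0.25). The TAM list, which also holds Tyro3 and Pros1, had a median of 0.42 (percentile 97.3). Type I interferon genes had a median of -1.18 and interferon gamma genes of -0.77 (both percentile 0), with Ifit1 at -2.62 (-2.95 to -2.30), Cxcl10 at -1.86 (-2.00 to -1.72) and Irf1 at -1.25 (-1.44 to -1.07). The genes that induce interferon were nearer 0 (-0.29, percentile 9.68). T cell attracting chemokines (-1.02, percentile 0.02) and inflammatory genes (-0.47, percentile 0.28; Nos2 -1.63, -1.97 to -1.29) were lower, and MHC class II genes higher (0.35, percentile 98.7; H2-Aa 0.45). By rank, Chil3 (-4.78), Ly6c2 (-3.32), Ifitm6 (-3.06) and Plac8 (-2.74) were lowest, along with Ifi206 (-3.78). The monocyte cluster was 24.5% of the class in KP vehicle and 10.4% in KPL vehicle. How far this mix enters into these ratios was not tested. Slc40a1 (3.61, 3.07 to 4.22), Gdf15 (2.61, 2.21 to 3.05), Syngr1 (2.96) and Cd209g (4.04) were highest. Bc1 had 606 against 0 UMIs, at least 35.3-fold higher.

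Dendritic cells had lower maturation genes in KPL (median -0.56, 1 of 14 genes above 0, percentile 0), among them Il12b at -1.68 (-2.12 to -1.24), Ccl22 at -1.07 (-1.22 to -0.92), Fscn1 at -1.04 (-1.20 to -0.87) and Cd40 at -0.83 (-1.16 to -0.51). This class mixes dendritic cell types: at Leiden resolution 2, migratory mature cells, led by Fscn1, Ccl22 and Ccr7 among others, were 30 beside 77 cDC2 cells in KP and 28 beside 175 in KPL. The MHC class II genes of the whole class had a median of 0.25 (percentile 98.8) and their type I interferon genes 0.22 (percentile 98.9). Siglech (3.89, 2.75 to 5.35), Ly6d (5.81) and Cox6a2 (170 against 0 UMIs, at least 19.99-fold higher) were the most raised. Siglech and Cox6a2 are among the markers used here for plasmacytoid dendritic cells, which had no cluster of their own. A few such cells in the class may carry this RNA, which was not tested. Cd209d (-1.94), Mfge8 (-1.83) and Brk1 (-1.62) were among the lowest. NK cells of KPL had lower cytotoxic genes (median -0.63, percentile 0): Gzmd had 1 against 354 UMIs (-7.18, -12.49 to -4.70), Gzme -3.40 (-5.04 to -2.14), and Gzmf 0 against 351 UMIs, at least 48.1-fold lower. Their type I interferon genes had a median of 0.02 (percentile 58.9). The NK class of KPL vehicle was only 59 cells, and every NK expression ratio with that library rests on them. How the granzyme UMIs were spread over NK cells was not tested, and the intervals do not cover it. Neutrophils had medians of -0.62 for type I interferon genes and -1.12 for interferon gamma genes, with Irf1 at -1.75 (-1.96 to -1.54) but Isg15 at 0.14 (0.09 to 0.19). Regulatory T cells had more RNA of their own genes (0.40, percentile 99.9; Il1rl1 0.64, 0.45 to 0.84), and conventional CD4 T cells had a type I interferon median of -0.22 (percentile 10.8).

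BGB324 against vehicle in KPL tumours asks what inhibition of AXL alone goes with. CD8 T cells were the most common gated T cells in the BGB324 library, with more Pdcd1, Lag3, Gzmb and Gzmk RNA per UMI than in KPL vehicle. Macrophages, regulatory T cells and dendritic cells were small shares, and neutrophils were most of the non-T immune cells. CD8 T cells, macrophages and monocytes, and neutrophils had higher type I interferon genes. Macrophage RNA such as Pf4, Folr2 and Ccl8 was far lower in the combined macrophage and monocyte class, in which the monocyte cluster held 90.5% of cells. Ratios of this class, its interferon genes included, may follow that mix of clusters.

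Of T cells, CD8 T cells were 62.8% (60.5 to 65.0), a log2 ratio of 1.64 (1.48 to 1.81). Regulatory T cells were 4.92%, 4.72-fold lower (a log2 ratio of -2.24, or -1.34 when gated after thinning), and conventional CD4 T cells 11.9%, close to KPL vehicle. Of non-T immune cells, macrophages and monocytes were 7.08% (6.02 to 8.26), 7.22-fold lower, with the macrophage cluster at 0.670% and the monocyte cluster at 6.41%. Neutrophils were 83.8% (82.2 to 85.4), dendritic cells 1.77% and NK cells 6.41%.

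CD8 T cells of BGB324 stood apart in the clustering, which had no batch integration: a T cell sub-cluster led by Cd8b1 and Cd8a among others held 833 cells of BGB324 and 2 of KPL vehicle, and one led by Nkg7 and Cd8a 20 and 100. Exhaustion genes of CD8 T cells had a median of 0.82 and cytotoxic genes of 0.96 (both percentile 100). Lag3 was 1.37 (1.24 to 1.49), Tigit 1.37 (1.22 to 1.52), Pdcd1 1.10 (0.99 to 1.21) and Havcr2 0.85 (0.57 to 1.14), beside Gzmk at 2.03 (1.73 to 2.35), Gzmb at 1.51 (1.43 to 1.59) and Ifng at 0.44 (0.24 to 0.65). The TCF1 progenitor genes had a median of -0.35 (percentile 0.35), with Tcf7 at -0.35 (-0.62 to -0.07), Ccr7 at -1.11 (-1.20 to -1.02) and Xcl1 at -1.09. Type I interferon genes had a median of 0.78 (19 of 21 genes above 0) and interferon gamma genes 0.35 (percentile 92.5), with Irf1 at 1.63 (1.42 to 1.85). Cell cycle genes were lower (-0.40, percentile 0.06; Stmn1 -1.45, Top2a -1.31). Glycolysis genes were higher (0.58, percentile 99.8; Eno1 2.02, 1.92 to 2.12, Pkm 1.11) and oxidative phosphorylation genes lower (-0.26, percentile 2.24). MHC class I genes (0.41, percentile 99.1; Tap2 0.89) and dissociation stress genes (0.62, percentile 100; Junb 1.22) were higher. By rank, Ikzf2 (-1.92, -2.05 to -1.79) and Slc45a4 (-2.13, -2.72 to -1.54) were lower. Apoe (-6.98) and Lyz2 (-4.44) were lower too, but Apoe was read in 51.3% of CD8 T cells of KPL vehicle, a level of free macrophage RNA found in every class there. Chtf8 (5.82, and higher in every class compared), Hist1h2ao (at least 45.7-fold), Hist1h2af (at least 19.7-fold) and Hist1h3i (at least 19.1-fold) were higher, the histone genes with 0 UMIs in CD8 T cells of KPL vehicle. The median gene of CD8 T cells had a log2 ratio of 0.14.

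The monocyte cluster held 90.5% of macrophages and monocytes in BGB324 and 10.4% in KPL vehicle. All ratios of this class may therefore follow the mix of clusters. Interferon gamma genes of macrophages and monocytes lay at a median of 2.13 and type I interferon genes at 1.68, with Irf1 at 3.47 (3.33 to 3.61), Irf7 at 2.62 (2.47 to 2.76) and Cxcl10 at 2.49 (2.34 to 2.64), and genes of interferon induction at 0.01. Complement and lipid genes had a median of -2.67 (0 of 12 genes above 0) and suppressive genes of -2.86, with Arg1 at -4.34 (-4.76 to -3.95), Folr2 at -5.94 (-8.22 to -4.39), Ccl8 at -4.82 (-5.17 to -4.49) and Pf4 at -6.83 (-7.40 to -6.32). Retnla had 0 against 2214 UMIs, at least 66.6-fold lower. Axl was -1.77 (-2.07 to -1.49) and Mertk -2.68 (-3.44 to -2.02), within a list median of -2.23, and Gas6 had 1 against 2010 UMIs (-7.50, -12.81 to -5.02), and Gdf15 1 against 1752 UMIs (-7.31, -12.61 to -4.83). MHC class II genes were higher (0.58; Ciita 2.48, 2.21 to 2.75), while inflammatory genes (0.22, percentile 81.4) and chemokines (0.25, percentile 65.7) lay within the random lists. The monocyte genes Ly6c2 (5.55) and Ace (5.90) ranked highest, and how much of this the mix of clusters gives was not tested. Neutrophils had interferon medians of 1.14 (type I, 22 of 22 genes above 0) and 1.79 (gamma), with Irf1 at 2.88 (2.68 to 3.08). NK cells had cytotoxic genes at 1.07 (percentile 100): Gzmd had 1160 against 1 UMIs (8.66, 6.18 to 13.97), Gzme 4.87 (3.63 to 6.50) and Gzmf 732 against 0 UMIs, at least 85.3-fold higher. Their type I interferon median was -0.05 (percentile 16.3). These NK ratios again rest on the 59 NK cells of KPL vehicle. Regulatory T cells had a median of 0.43 for their own genes (percentile 99.2), with Ccr8 at 1.10 (0.90 to 1.29) and Il1rl1 at -1.57 (-1.89 to -1.27), and conventional CD4 T cells had a type I interferon median of 0.62. Median genes were at 0.11 in regulatory T cells and 0.13 in NK cells. Dendritic cells were too few (37) to compare.

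PD-1 blockade alone against vehicle asks how KPL tumours take the antibody. NK cells were a larger share than in KPL vehicle, and macrophages and monocytes together a smaller one. CD8 T cells had more Ccl5, Gzmk and Gzmf RNA and slightly more Tcf7 and Lef1 RNA, with less RNA of cell cycle genes. Macrophages and monocytes had more Cxcl9, Cxcl10 and Nos2 RNA and other interferon-response genes.

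NK cells were 11.1% of non-T immune cells, 5.27-fold higher, and the monocyte cluster was 14.5% (294 cells, but 535 without doublet removal). Macrophages and monocytes together were 27.8% (25.9 to 29.8), 1.84-fold lower, neutrophils 53.1% (50.9 to 55.3), and dendritic cells 6.04%. CD8 T cells were 25.2% (23.7 to 26.8) of T cells, a log2 ratio of 0.33 (0.15 to 0.51), and conventional CD4 T cells 17.3%. Regulatory T cells were 14.7%, a log2 ratio of -0.66 (-0.84 to -0.46) that shrank to -0.076 when cells were gated after thinning to equal depth.

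In CD8 T cells, the TCF1 progenitor genes had a median of 0.30 (percentile 99.5), with Tcf7 at 0.30 (0.02 to 0.59), Lef1 at 0.64 (0.27 to 1.02) and S1pr1 at 0.65 (0.33 to 0.99). Cytotoxic genes had a median of 0.23 (percentile 99.4), with Gzmf at 2.94 (2.02 to 4.03), Gzmk at 1.17 (0.84 to 1.51) and Ccl5 at 0.73 (0.68 to 0.78), and exhaustion genes 0.18 (percentile 97.8), with Pdcd1 at 0.35 (0.22 to 0.47). Interferon genes had medians of 0.37 (type I, 19 of 20 genes above 0) and 0.48 (gamma, 12 of 13), with Bst2 at 0.70 (0.44 to 0.98). Cell cycle genes were lower (-0.37, percentile 0), Ube2c at -0.89 (-1.08 to -0.69). MHC class I (0.13, percentile 92.3), hypoxia and glycolysis (-0.05, percentile 22.7), oxidative phosphorylation (-0.09, percentile 17.4) and dissociation stress genes (-0.13, percentile 2.45) were nearer 0. Hypk (3.97), Hist1h2ai (5.87) and Hist1h2ao (at least 98.7-fold) ranked highest and Olfr1369-ps1 (-6.86) lowest, genes for which KPL vehicle stood out over all cells. Apoe (-3.75) and C1qb (-3.64) again followed the free macrophage RNA of KPL vehicle. Gstp3 (1.70, 1.33 to 2.09), Ly6c2 (1.46, 1.27 to 1.66) and Reep5 (1.40, 1.22 to 1.59) were highest by the later ranking and Cops6 (-1.17, -1.48 to -0.87) among the lowest.

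Macrophages and monocytes had interferon medians of 1.04 (type I) and 1.19 (gamma, 14 of 14 genes), with Ifit1 at 2.27 (1.93 to 2.60), and 0.17 (percentile 82.2) for interferon induction. Chemokines had a median of 0.73, with Cxcl10 at 2.05 (1.92 to 2.17) and Cxcl9 at 0.88 (0.82 to 0.93), and inflammatory genes 0.48, with Nos2 at 1.92 (1.61 to 2.22). Complement and lipid genes (-0.98, 0 of 12), suppressive genes (-0.42) and the TAM list (-0.64) were lower. Among them were Il10 at -2.30 (-2.80 to -1.83), Gas6 at -2.16 (-2.47 to -1.85) and Axl at -0.68 (-0.82 to -0.55), whereas Arg1 was 0.70 (0.64 to 0.75). The macrophage cluster was 89.6% of this class in KPL vehicle and 47.7% here, so these medians may follow the mix of clusters. MHC class II genes had a median of 0.09 (percentile 70.7). Lyve1 had 2 against 503 UMIs (-5.68, -8.73 to -3.82), Cd209f 0 against 421 UMIs, at least 28.6-fold lower, and Bc1 was at least 41.2-fold lower, while the monocyte genes Chil3 (4.72) and Ly6c2 (3.87) ranked highest. Dendritic cells had a maturation median of 0.14 (percentile 87.7; Ccl22 -1.02, -1.26 to -0.77), an MHC class II median of -0.09 (percentile 9.28) and a type I interferon median of 0.23 (percentile 96.8), with Ccl3 (2.40), Cd7 (2.04) and Cd209d (2.03) highest and Fcrls (-3.60) and Aldh1a2 (-3.66) lowest. Neutrophils had interferon medians of 0.52 (type I) and 0.94 (gamma). NK cells had a cytotoxic median of 0.19 (percentile 96.4; Gzma 0.71, 0.62 to 0.81, Gzmc -1.50, -1.60 to -1.40) and a type I interferon median of -0.23 (percentile 10.1). The KPL vehicle side of these NK ratios was 59 cells. Regulatory T cells had a median of 0.11 for their own genes (percentile 93.0; Ikzf2 0.45, 0.39 to 0.52), and conventional CD4 T cells a type I interferon median of -0.23 (percentile 0.73).

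The combination against KPL vehicle asks whether inhibition of AXL together with PD-1 blockade goes with different immune cells. Neutrophils and CD8 T cells were larger shares, and macrophages, dendritic cells and regulatory T cells smaller. CD8 T cells had more Gzmk, Gzmf, Ccl5, Gzmb and Ifng RNA and more of the type I interferon genes, less of the cell cycle genes, and a Tcf7 level whose interval included 0. Macrophages and monocytes had more Cxcl10, Il12b and Nos2 RNA and less of Retnla, Cd163, Folr2 and Gas6.

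Neutrophils were 84.6% (83.4 to 85.8) of non-T immune cells, macrophages and monocytes 9.64% (8.68 to 10.7), 5.30-fold lower, dendritic cells 1.18%, 6.03-fold lower, and NK cells 4.36%. As a share of T cells, CD8 T cells were 44.3% (42.1 to 46.5), 2.20-fold higher, regulatory T cells 6.81%, 3.41-fold lower (2.40% against 5.93% of T cells in KPL vehicle when gated after thinning), and conventional CD4 T cells 16.3%.

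Type I interferon genes of CD8 T cells had a median of 0.88, with 20 of 20 genes above 0, among them Ifit1 at 2.18 (1.32 to 3.17) and Bst2 at 1.05 (0.80 to 1.31), and interferon gamma genes one of 0.36 (percentile 99.7). Cytotoxic genes had a median of 0.47 (percentile 100), with Gzmf at 3.11 (2.20 to 4.20), Gzmk at 1.46 (1.14 to 1.79), Ccl5 at 1.05 (1.00 to 1.10), Ifng at 0.88 (0.67 to 1.09) and Gzmb at 0.75 (0.66 to 0.83). Exhaustion genes had a median of 0.48 (percentile 100), with Tigit at 0.87 (0.71 to 1.03) and Havcr2 at 0.49 (0.18 to 0.81) but Pdcd1 at 0.12 (-0.00 to 0.25). The TCF1 progenitor genes had a median of -0.17 (percentile 5.21), with Tcf7 at -0.17 (-0.47 to 0.13), Slamf6 at -0.10 (-0.53 to 0.34) and Ccr7 at -1.22 (-1.33 to -1.12). Cell cycle genes were lower in 15 of 15 (median -1.09), among them Ube2c at -1.53 (-1.74 to -1.32) and Top2a at -1.46 (-1.61 to -1.31), and outside the list Nusap1 was -1.73 (-2.11 to -1.37) and Asf1b -1.72 (-2.19 to -1.26). Dissociation stress genes were higher (0.63, percentile 100; Hspa1b 2.06, 1.78 to 2.34, Hspa1a 1.91, 1.67 to 2.16). A T cell sub-cluster led by Hspa1a, Hspa1b, Ccl4 and Ifng among others held 23 of 1336 T cells in KPL vehicle and 97 of 2056 in the combination. How far the Ifng and stress gene ratios follow it was not tested. MHC class I genes had a median of 0.23 (percentile 99.6), hypoxia and glycolysis genes 0.02 (percentile 52.9) and oxidative phosphorylation genes -0.25 (percentile 0.15). Lcn4 (3.78, 2.38 to 5.68), Mrps6 (2.46, 2.13 to 2.80), Sap18b (4.90) and Dynlt1f (4.05), the last 3 of them low in every class of KPL vehicle, and Hypk (4.52), Ftl1-ps1 (3.91) and Hist1h2ao (at least 193-fold), low over all cells there, ranked highest. Olfr1369-ps1 (-7.00), Wdr89 (-1.65) and Hist2h2aa1 (-2.98), whose counts may depend on how near-identical copies were read, and Apoe (-3.13), C1qb (-3.26) and Lyz2 (-2.86), read as free RNA in KPL vehicle, ranked lowest.

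Macrophages and monocytes had interferon medians of 1.06 (type I) and 1.46 (gamma, 14 of 14), with Iigp1 at 2.31 (2.14 to 2.49), and 0.06 (percentile 67.8) for interferon induction. Chemokines (1.04; Cxcl10 2.16, 2.03 to 2.29) and inflammatory genes (0.81; Il12b 3.40, 2.80 to 4.01, Nos2 1.85, 1.52 to 2.17) were higher. Suppressive genes (-1.26), complement and lipid genes (-1.11, 0 of 12) and the TAM list (-0.77) were lower. Retnla had 2 against 2214 UMIs (-7.54, -10.58 to -5.68), Cd163 2 against 581 UMIs (-5.61, -8.65 to -3.75), Folr2 -3.29 (-3.81 to -2.80), Gas6 -2.81 (-3.26 to -2.40) and Axl -0.93 (-1.09 to -0.77), with Arg1 at 0.25 (0.18 to 0.31). MHC class II genes were near 0 (-0.05, percentile 16.1). Lyve1 had 0 against 503 UMIs, at least 28.1-fold lower, Cd209f at least 23.5-fold, and Hspb1 1 against 479 UMIs (-6.33, -11.63 to -3.84). Ly6c2 (5.62), Chil3 (4.94), Plac8 (3.64) and Ifi205 (3.95) ranked highest. The macrophage cluster was 58.0% of the class, against 89.6% in KPL vehicle. At Leiden resolution 2, a macrophage cluster led by Ccl7, Ccl8, Mrc1, Folr2 and Cd163 among others held 225 cells of KPL vehicle and 5 of the combination. The whole class held 1433 and 336 cells at resolution 1. These ratios and the list medians may partly follow that mix, which was not tested. Neutrophils had interferon medians of 0.91 (type I, 22 of 22) and 1.56 (gamma; Gbp2 2.06, 1.93 to 2.19), where the median gene was at -0.13. Gbp2 is also among the leading genes of neutrophil cluster 1, which was 1.11% of neutrophils in KPL vehicle, 17.1% in BGB324 and 28.0% in the combination, so the mix of neutrophils moved with these medians. NK cells had a cytotoxic median of 0.56 (percentile 100; Gzma 1.04, 0.95 to 1.14) and a type I interferon median of -0.05 (percentile 50.4). The KPL vehicle side of these NK ratios was 59 cells. Regulatory T cells had a median of -0.10 for their own genes (percentile 39.5; Il1rl1 -0.97, -1.21 to -0.73), conventional CD4 T cells a type I interferon median of 0.29 (percentile 94.1). The 41 dendritic cells were too few to compare.

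**Figure D2:**
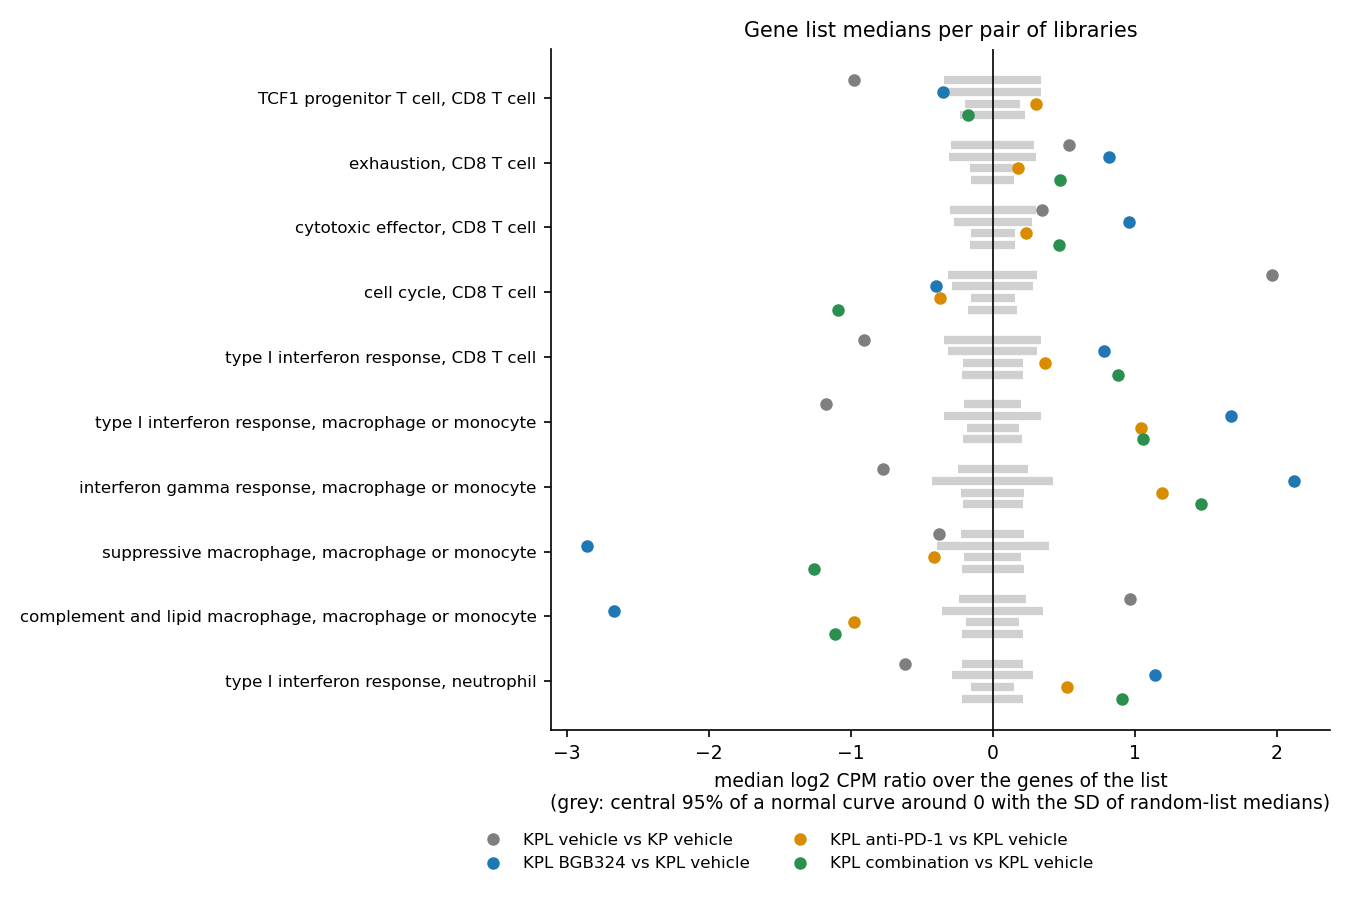
Median log2 CPM ratio of gene lists for 4 pairs of libraries (points), with grey bars for the central 95% of a normal curve around 0 with the SD of medians of random lists. Random lists need not centre on 0, so the bars can differ from the percentiles in the text. In CD8 T cells, the cell cycle median was 1.97 for KPL vehicle against KP vehicle and -1.09 for the combination against KPL vehicle.

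Set against PD-1 blockade alone, the combination asks what the AXL inhibitor adds to it. Its CD8 T cells had more Ifng, Cd69, Hspa1a and Hspa1b RNA and less Tcf7, S1pr1 and Ccr7 RNA, and it held more CD8 T cells among T cells and fewer regulatory T cells. Macrophages and monocytes had less Retnla, Cd163 and Gpnmb RNA.

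Of T cells, a larger share were CD8 T cells, by a log2 ratio of 0.81 (0.70 to 0.93), regulatory T cells were 2.16-fold lower, and conventional CD4 T cells differed by -0.08. Neutrophils were 1.59-fold higher among non-T immune cells, macrophages and monocytes 2.88-fold, dendritic cells 5.13-fold and NK cells 2.54-fold lower. In CD8 T cells, the TCF1 progenitor genes had a median of -0.45, with 12 of 13 genes below 0, at percentile 0, among them S1pr1 at -1.28 (-1.57 to -0.99), Ccr7 at -0.88 (-0.97 to -0.79) and Tcf7 at -0.47 (-0.71 to -0.24). Type I interferon genes had a median of 0.42 (20 of 21 above 0; Ifi27l2a 0.68, 0.62 to 0.74), interferon gamma genes one of -0.12 (percentile 11.1), and cell cycle genes one of -0.60 (0 of 15). Cytotoxic genes had a median of 0.18 (percentile 99.9), with Ifng at 0.87 (0.71 to 1.04) and Gzmb at 0.43 (0.37 to 0.50), though the mean of that list was -0.026. Exhaustion genes had a median of 0.12 (percentile 97.4; Pdcd1 -0.22, -0.32 to -0.12). Dissociation stress genes were higher (0.75, percentile 100; Hspa1a 2.15, 1.95 to 2.35, Hspa1b 2.03, 1.82 to 2.24, Fos 1.21), and Cd69 was 1.33 (1.18 to 1.48). MHC class I genes had a median of 0.17 (percentile 99.7). Glycolysis (0.05, percentile 76.5) and oxidative phosphorylation genes (-0.02, percentile 26.5) were near 0. A T cell sub-cluster led by Hspa1a, Hspa1b, Ccl4 and Ifng among others held 45 of 3034 T cells in anti-PD-1 and 97 of 2056 in the combination. How far the Ifng and stress gene ratios follow this sub-cluster was not tested. Myb (-1.22, -1.51 to -0.93) and Trf (-1.66, -2.12 to -1.23) were lower. S100a8 (2.64) and S100a9 (2.18) ranked high and Krt8 (-5.54) and Krt18 (-3.71) low, at about 1% or less of their level in neutrophils or in epithelial or tumour cells.

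The suppressive genes of macrophages and monocytes had a median of -0.34 (percentile 0.11), with Retnla at 2 against 140 UMIs (-5.85, -8.90 to -3.97), Cd163 at -5.40 (-8.47 to -3.51), Gpnmb at -1.16 (-1.46 to -0.87) and Arg1 at -0.45 (-0.52 to -0.37), and Atp6v0d2 was -2.32 (-2.91 to -1.76). At Leiden resolution 2, a macrophage cluster led by Ccl7, Ccl8, Mrc1, Folr2 and Cd163 among others held 24 cells of anti-PD-1 and 5 of the combination. The whole class held 562 and 336 cells at resolution 1. These ratios may follow the mix of macrophages, which was not tested. Interferon medians were -0.04 (type I) and 0.17 (gamma), that of induction genes 0.04, MHC class II -0.14, inflammatory genes 0.14, complement and lipid genes -0.04, chemokines -0.07 and the TAM list -0.30, with Iigp1 at 1.53 (1.30 to 1.78) and C4b at 2.26 (1.65 to 2.91). Neutrophils had medians of 0.50 and 0.54 for type I and gamma genes, over a median gene at -0.13, and Gbp4 at 1.81 (1.48 to 2.15). NK cells had a cytotoxic median of 0.54 (Ifng 1.38, 0.92 to 1.84, Gzmb 0.89, 0.75 to 1.04) and a type I interferon median of 0.45. Conventional CD4 T cells had a type I interferon median of 0.52 (15 of 16 above 0). Regulatory T cells had a median of -0.17 for their own genes (percentile 1.97), with Il10 at -0.92 (-1.49 to -0.38) and Ctla4 at -0.46 (-0.57 to -0.35).

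Set against BGB324 alone, the combination asks what PD-1 blockade adds. CD8 T cells of these libraries lay apart in the clustering: the T cell sub-cluster led by Cd8b1, Cd8a and Cd160 among others held 833 cells of BGB324 and 21 of the combination, and the one led by Nkg7 and Cd8a 20 and 481. Those of the combination had less Pdcd1, Cd160, Lag3, Gzmb and Tbx21 RNA, and its macrophage and monocyte class held more macrophages, with more Arg1, Pf4 and Nos2 RNA. CD8 T cells were 1.42-fold lower among T cells and regulatory T cells higher by a log2 ratio of 0.47 (0.09 to 0.85), which was 0.033 when gated after thinning and 1.05 by T cell sub-clusters. Conventional CD4 T cells were higher by 0.46. Neutrophils differed by 0.01 (-0.02 to 0.05), macrophages and monocytes were 1.36-fold higher, NK cells 1.47-fold lower, and dendritic cells differed by -0.59 (-1.25 to 0.08).

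Exhaustion genes of CD8 T cells had a median of -0.34 (percentile 3.88; Cd160 -1.29, -1.44 to -1.15, Pdcd1 -0.98, -1.06 to -0.90, Lag3 -0.82, -0.90 to -0.74) and cytotoxic genes -0.35 (percentile 0.96; Tbx21 -1.37, -1.60 to -1.15, Gzmb -0.76, -0.81 to -0.72), but Gzmf was 1.08 (0.78 to 1.39). TCF1 progenitor genes had a median of -0.12 (percentile 38.3; Tcf7 0.18, -0.04 to 0.40, Bcl6 1.27, 0.77 to 1.77). Type I interferon genes were at 0.28 (percentile 99.7), interferon gamma genes at -0.03 (Irf1 -0.93, -1.06 to -0.80), cell cycle genes at -0.40 (percentile 0.87), MHC class I at -0.17, glycolysis at -0.51 (percentile 0.20; Pkm -1.16, -1.23 to -1.09, Eno1 -1.02, -1.07 to -0.96), oxidative phosphorylation at -0.00 and dissociation stress genes at 0.07. Hspa1b (2.73, 2.54 to 2.91), Hspa1a (1.99, 1.85 to 2.13) and Mid1 (2.59) ranked highest, and Chtf8 (-4.42), Scamp4 (-3.03), Kcna3 (-3.03), Slc26a10 (-2.53), Ctse (-2.52) and Tnfaip8l2 (-1.76) lowest. All of these lowest genes but Slc26a10 had their highest CPM in BGB324 in every class with at least 50 cells there, so they are not particular to its CD8 T cells. Higher in macrophages and monocytes were suppressive (1.63), complement and lipid (1.40, 12 of 12) and TAM-list genes (1.45, with Mertk at 2.07, 1.35 to 2.86, and Axl at 0.84, 0.52 to 1.17). Arg1 was 4.59 (4.19 to 5.01), Pf4 5.72 (5.21 to 6.29), Ccl12 4.36 (3.72 to 5.08) and Ccl8 3.32 (2.98 to 3.68). The macrophage cluster was 9.46% of this class in BGB324 and 58.0% in the combination, so its ratios may follow the mix of clusters. Inflammatory genes (0.84; Nos2 4.08, 2.69 to 5.98) and chemokines (0.76) were higher, and MHC class II (-0.56; Ciita -1.59, -1.95 to -1.23), type I interferon (-0.69; Irf7 -1.48, -1.67 to -1.30), interferon gamma (-0.56) and induction genes (-0.16) lower, as were Ace (-3.13), Adgre4 (-2.61) and again Kcna3 (-3.83). Neutrophils had interferon medians of -0.13 and -0.63 for type I and gamma genes. NK cells had a cytotoxic median of -0.64, with Gzme at -4.16 (-4.89 to -3.52) and Gzmd at -4.18 (-4.60 to -3.79), and a type I median of 0.07. Regulatory T cells had a median of -0.45 for their own genes (Ccr8 -1.12, -1.39 to -0.86), conventional CD4 T cells a type I interferon median of -0.09. Median genes were at -0.11 in CD8 T cells, regulatory T cells and NK cells, and at -0.20 in neutrophils.

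Genes foreign to CD8 T cells were read in them for carried-over RNA. Neutrophil genes had medians of 0.87 (KPL against KP), -1.40 (BGB324), -1.24 (anti-PD-1) and 0.26 (combination, each against KPL vehicle), then 1.41 and 1.70 for the combination against anti-PD-1 and against BGB324. These medians do not gauge the RNA by themselves: S100a8 in CD8 T cells was 28.7 CPM in KP vehicle, 7.38 in KPL vehicle, 17.1 in BGB324, 11.0 in anti-PD-1 and 68.9 in the combination, opposite in direction to 3 of the first 4 medians. Fibroblast and tumour genes had -1.76 with BGB324, 1.76 with anti-PD-1, -1.96 with the combination and -3.71 for the combination against anti-PD-1, and too few of these genes were read in the other pairs. The medians of neutrophil genes with BGB324 and of fibroblast and tumour genes with anti-PD-1 reversed sign under another minimum of UMIs per gene. Erythrocyte genes gave no median in CD8 T cells, as fewer than 3 of them had 20 UMIs. Free haemoglobin RNA was seen in BGB324: Hbb-bs was read in 7.83% (6.34 to 9.55) of its CD8 T cells and in 5.97% to 10.1% of cells of each class there, against 0.743% (0.090 to 2.66) of CD8 T cells in KPL vehicle and 0.522% (0.142 to 1.33) in anti-PD-1, at median depths of 8496.5, 7337 and 4759.5 UMIs.

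Because the study is about TCF1-positive CD8 T cells, shares of CD8 T cells with a Tcf7 UMI were taken after thinning each cell to 1500 UMIs. KP vehicle had the largest share, 26.5% (20.9 to 32.7) of 230 cells. KPL vehicle had 8.02% (5.03 to 12.0) of 262, BGB324 7.13% (5.68 to 8.82) of 1094, anti-PD-1 12.8% (10.4 to 15.4) of 736, and the combination 7.19% (5.58 to 9.09) of 890. Within KPL, the log2 ratio to vehicle was -0.17 (-0.84 to 0.57) with BGB324, 0.67 (0.02 to 1.40) with anti-PD-1 and -0.16 (-0.84 to 0.60) with the combination, and the combination lay below anti-PD-1 by -0.83 (-1.28 to -0.38). The ratio for anti-PD-1 was -0.04 without thinning. Neutrophils, which lack Tcf7, had it in 0 to 0.598% of cells, the 0 in KP vehicle with an upper limit of 0.287%. Median depths before thinning were 4223, 7416.5, 8717, 4861.5 and 4828 UMIs in CD8 T cells and 1990.5, 2463, 2951.5, 2030.5 and 2298.5 in neutrophils, in the library order used above. Without thinning the Tcf7 shares were 45.8%, 24.9%, 22.1%, 24.2% and 15.6%, and thinning left out 10, 7, 42, 30 and 21 cells. Taken over all T cells, a denominator added later, Tcf7-positive CD8 T cells were 4.55%, 1.71%, 4.69%, 3.42% and 3.34%.

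CD8 T cells with both Tcf7 and Pdcd1 were 1.74%, 1.15%, 2.56%, 3.53% and 1.01%, and those with Tcf7 and Slamf6 4.35%, 1.15%, 0.823%, 2.04% and 0.562%. Pdcd1 was found in 12.2% (8.24 to 17.1) of KP vehicle CD8 T cells, 34.7% (29.0 to 40.8) in KPL vehicle, 46.3% (43.4 to 49.4) with BGB324, 36.5% with anti-PD-1 and 33.1% with the combination, against 0.117% to 1.66% of neutrophils and, without thinning, 25.4% to 74.2% of CD8 T cells. Havcr2 with Pdcd1 was found in 1.30%, 1.15%, 7.22%, 2.85% and 3.60%, where the combination lay above KPL vehicle after thinning and below it without. Mki67 was read in 2.17% (5 of 230 cells) of KP and 12.98% (9.16 to 17.7) of KPL vehicle CD8 T cells, 7.22% with BGB324, 9.10% with anti-PD-1 and 5.62% with the combination, beside 1.23% to 3.48% of neutrophils, and without thinning in 6.25%, 27.9%, 19.6%, 19.8% and 14.6%. Gzmb was found in 26.1%, 33.2%, 47.6%, 38.7% and 43.4% of CD8 T cells and in 0.312% to 4.26% of neutrophils, and without thinning in 35.8% to 62.9% of CD8 T cells.

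**Figure D3:**
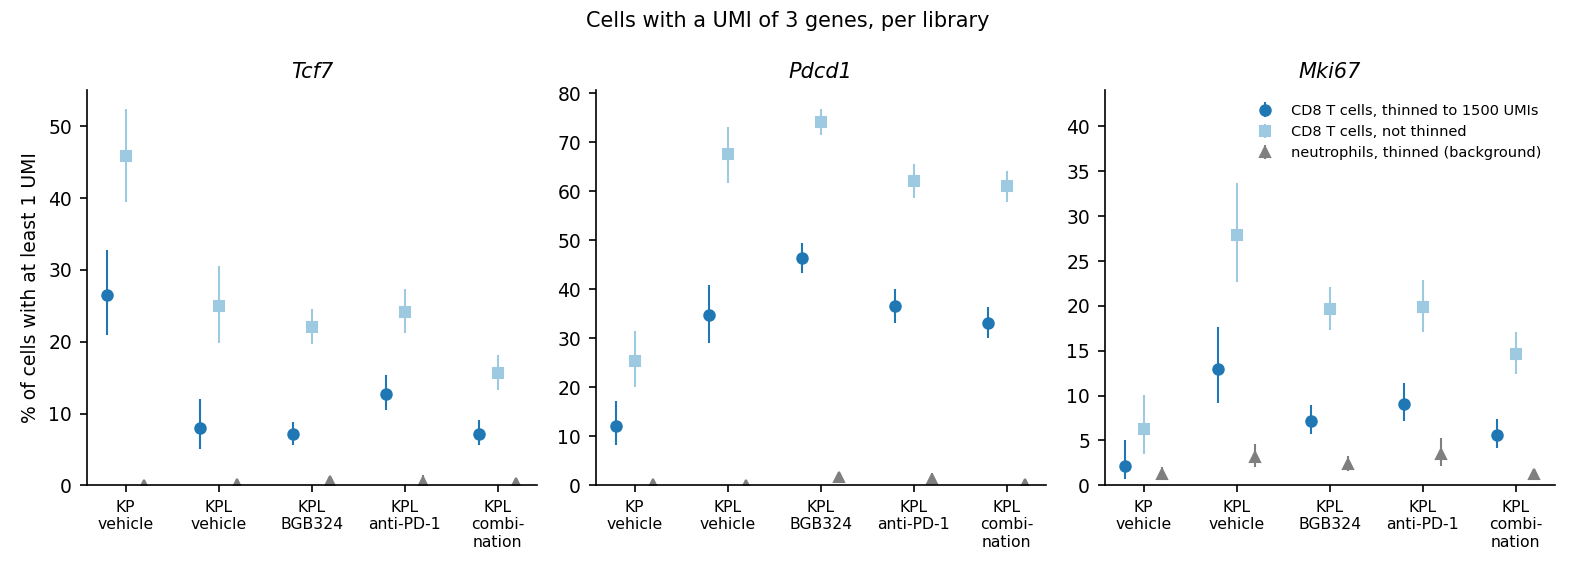
Percent of CD8 T cells with a UMI of Tcf7, Pdcd1 or Mki67 in each library, thinned to 1500 UMIs and not thinned, and of thinned neutrophils as background, with exact 95% intervals. Tcf7 was found in 26.5% of CD8 T cells of KP vehicle and in 7.13% to 12.8% in the KPL libraries after thinning.

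TCR sequences show how far T cells of a library share a clonotype. Drawn down to 322 barcodes per library, 8.07% of barcodes lay in clonotypes of 2 or more in KP vehicle, 14.4% (10.2 to 18.3 over 1000 draws) in KPL vehicle, 17.7% (13.04 to 22.7) in anti-PD-1 and 30.4% (25.2 to 36.0) in the combination. With clonotypes defined by the TRB nucleotide sequence these were 14.6%, 23.7%, 31.5% and 44.3%. Over all 322, 789, 927 and 1117 barcodes the shares were 8.07%, 22.1%, 30.4% and 44.8%. Equal draws do not even out the mix of subsets. Of T cells with a TRB chain, CD8 T cells were 69 of 292, 211 of 691, 368 of 832 and 632 of 1011. In each library they lay in expanded clonotypes more often than regulatory T cells did, so the drawn shares may partly follow this mix. Within subsets no drawing to equal numbers was made, and the shares rise with the number of barcodes read, so they are not on a par between libraries. Expanded clonotypes held 13.04% (6.14 to 23.3) of CD8 T cells with a TRB chain in KP vehicle, 39.8% (33.2 to 46.8) in KPL vehicle, 39.7% (34.6 to 44.9) in anti-PD-1 and 61.4% (57.5 to 65.2) in the combination. Conventional CD4 T cells had 12.0%, 19.0%, 43.4% and 23.8%, and regulatory T cells 6.82%, 11.4%, 11.2% and 2.27%. A TRB chain was found in 28.8%, 78.4%, 48.0% and 69.4% of CD8 T cells of these libraries, so the KP share rests on 69 cells. The largest clonotypes had 4, 22, 12 and 55 barcodes: that of the combination used TRBV10 and TRBJ2-3, with 43 barcodes in the CD8 gate, and that of anti-PD-1 used TRBV16 and TRBJ2-5, with its 12 barcodes in the CD4 gates. The TCR library of KPL BGB324 was not among the files used.

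Expanded CD8 T cells of the KPL libraries with TCRs held Tcf7 in smaller shares than those in clonotypes of 1 barcode, a difference that was not tested. Cells in clonotypes of 1 can still share their TRB sequence with another clonotype. The shares, without thinning, were 15.5% (8.51 to 25.0) against 33.1% (25.0 to 42.0) in KPL vehicle, 13.01% (8.02 to 19.6) against 30.6% (24.6 to 37.1) in anti-PD-1 and 8.25% (5.71 to 11.4) against 27.5% (22.0 to 33.5) in the combination. In KP vehicle, 1 of 9 expanded cells had Tcf7, 11.1% (0.281 to 48.2), against 45.0% (32.1 to 58.4), too few to tell. Pdcd1 was found in 66.7% against 40.0% in KP vehicle and, in the order above, 84.5% against 66.1%, 73.3% against 68.9% and 74.0% against 62.3%. In the order KP vehicle, KPL vehicle, anti-PD-1 and combination, the median depths of these cells differed little, at 5513 and 5466, 8065 and 8203, 6287.5 and 6309.5, and 5374.5 and 5586 UMIs.

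**Figure D4:**
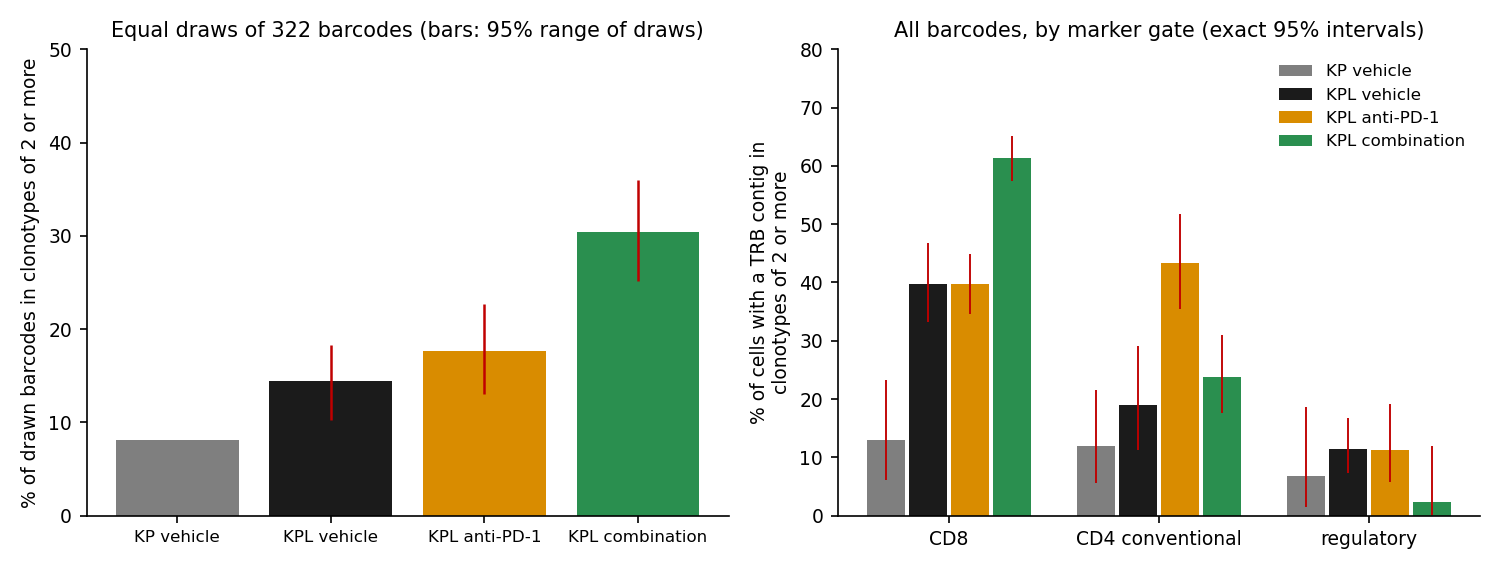
Percent in clonotypes of 2 or more in 4 libraries, of barcodes drawn to equal numbers (left, lines for the 95% range of draws) and of CD8, conventional CD4 and regulatory T cells with a TRB chain (right, not drawn, exact 95% intervals). The combination had 30.4% and KP vehicle 8.07% after drawing to equal numbers, over barcodes of all subsets together.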

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

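The tests of the histone and CD8 share patterns below were chosen only after the result was seen. Epithelial or tumour cells appeared in a sort for CD45-positive cells that should exclude them, and are flagged for that reason. They were 2.03% of kept cells in KP vehicle, 7.43% in KPL vehicle, 0.586% in KPL BGB324, 10.9% in KPL anti-PD-1 and 0.912% in the KPL combination, from 97, 332, 23, 620 and 51 cells. Their cluster is led by Krt8, Krt18 and Wfdc2. Axl in these cells was 115 CPM in KP vehicle, 69.5 in KPL vehicle and 83.7 in anti-PD-1. No explanation was tested for the differences between these shares, which the purity of each sort alone can set.

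CD8 T cells were 20.1% of T cells in KPL vehicle and 62.8% in KPL BGB324. Deeper reading of each cell would leave no difference after thinning, but thinned to 1500 UMIs the log2 ratio was 1.80 (1.62 to 1.99). Free Cd8a and Cd8b1 RNA would mark other cells too, but 3.92% of BGB324 neutrophils had such a UMI after thinning, against 61.7% of T cells in the gate. An effect of BGB324 and a difference between the pooled tumours both stay open, since 1 library each cannot separate them.

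Hist1h2ao was nearly absent from KPL vehicle, at 0.0482 CPM over all cells against 29.1 to 95.7 CPM in the other 4 libraries. Fewer dividing cells would lower cell cycle genes as well, but their median in CD8 T cells was 1.97 higher in KPL vehicle than in KP vehicle on the log2 scale. A different division of UMIs between near-identical copies may be the source: Hist1h2ao was 0.00637% of the UMIs of Hist1h2ao and Hist1h2ap in KPL vehicle and 4.57% to 22.4% elsewhere, and it was lowest in KPL vehicle in 6 of 7 classes. NK cells tied with another library at 0, and no sequences were at hand to follow the copies, so this stays open. The same holds for any pair of libraries that includes KPL vehicle and a gene with such copies.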

How the results depend on the processing

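Tests chosen only after the result was seen are the Tcf7 shares over all T cells and the list medians over genes high in their own class. Under alternatives, 142 of 144 ratios of non-T immune class shares kept their sign, as did 137 of 144 T cell subset ratios. Signs were also kept by 74 of 94 ratios of CD8 gene shares, 935 of 973 list medians and 4063 of 4129 gene ratios. In that order, 14, 16, 13, 51 and 492 lay outside the interval in the same direction or uncalled. Those reversed were 0, 0, 3, 4 and 17. Clonal shares are percents, which cannot change sign, and 9 of 32 lay outside the interval or range of draws. Over all lists and classes, 60 of 4216 medians reversed, and over all genes the rule names 88 of 14790. The cause was not tested for any value below, except where the construction of an alternative shows it. CD8 T cells with a TRB contig gave no value for pairs with BGB324, and 11 list medians had too few genes at a floor of 100 UMIs.

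At most 5% mitochondrial UMIs gave neutrophil ratios of -0.82 for KPL vehicle against KP vehicle (-0.90 in the report), 1.01 for BGB324 (1.13), 0.365 for anti-PD-1 (0.47) and 1.02 for the combination (1.14) against KPL vehicle. In KPL vehicle against KP vehicle it gave 1.59 for macrophages or monocytes (1.42), with no cDC2 cluster and a monocyte cluster led by H2-Ab1 among others, which may hold those cells, and 1.01 for regulatory T cells (1.28), and no doublet removal gave 1.30 for macrophages or monocytes. Leiden resolution 2 gave neutrophil ratios of 0.372 for anti-PD-1 against KPL vehicle and 0.76 for the combination against anti-PD-1 (0.67), and at least 1000 UMIs gave 0.31 and 0.81. With T cell sub-clusters the CD8 T cell ratio of KPL vehicle to KP vehicle was 0.74 (0.32), and regulatory T cell ratios were 0.97 there, -0.41 for anti-PD-1 (-0.66) and -1.29 for the combination (-1.77) against KPL vehicle, and 1.05 for the combination against BGB324 (0.47). The sub-clusters counted as regulatory include one led by Calca, Il13 and Areg, innate lymphoid genes, with 82 cells of anti-PD-1 and 4 of KPL vehicle, and one of 69 cells led by Tyrobp and Thbs1, so these ratios do not hold regulatory T cells alone. Gating after thinning gave regulatory T cell ratios of 0.92 for KPL vehicle against KP vehicle, -1.34 for BGB324 (-2.24), -0.076 for anti-PD-1 against KPL vehicle and 0.033 for the combination against BGB324, and -1.31 for the regulatory T cell share: KPL combination vs KPL vehicle. Thinning removes Foxp3 and Cd4 UMIs from deep cells, so fewer pass the gate.

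Tcf7 shares of CD8 T cells gave, without thinning, -0.88 for KPL vehicle against KP vehicle (-1.73), a reversed -0.044 for anti-PD-1 against KPL vehicle (0.67) and -0.50 for the combination against BGB324 (0.01). At least 2 Tcf7 UMIs gave -0.86, a reversed -0.31 and -0.55 for these pairs and -0.97 for the combination against KPL vehicle (-0.16). Over all T cells the ratios were 1.46 for BGB324 (-0.17) and 0.97 for the combination against KPL vehicle, -0.034 for the combination against anti-PD-1 (-0.83) and -0.49 against BGB324. Havcr2 with Pdcd1, combination against KPL vehicle, reversed from 1.65 to -0.18 without thinning.

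In CD8 T cells, a floor of 100 UMIs gave type I interferon genes -0.30 for KPL vehicle against KP vehicle (-0.91) and reversed neutrophil genes to 0.39 for BGB324 against KPL vehicle (-1.40), which no doublet removal put at 0.011. No doublet removal gave type I interferon genes 0.60 for anti-PD-1 (0.37), and a floor of 1 UMI reversed fibroblast and tumour genes there to -0.068 (1.76). Only genes high in their own class gave type I interferon -0.90 in macrophages, KPL vehicle against KP vehicle (-1.18), and 0.46 in CD8 T cells, BGB324 (0.78). Means gave -2.33 for suppressive macrophage genes in macrophage or monocyte: KPL BGB324 vs KPL vehicle (-2.86), 0.44 for cytotoxic genes with anti-PD-1 (0.23), -0.90 for cell cycle genes with the combination (-1.09), and, combination against anti-PD-1, a reversed -0.026 for cytotoxic genes (0.18) and -1.04 for suppressive genes (-0.34).

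Single genes that reversed with no doublet removal were, in CD8 T cells, Acod1 (0.18), S100a9 (-0.74) and S100a8 (-0.85) with BGB324, S100a9 (-0.68) with anti-PD-1 and Il1r2 (0.054) with the combination, and Ifi27l2a (-0.12) in dendritic cells, KPL vehicle against KP vehicle. The mean of each cell's CPM reversed Ccl4 in CD8 T cells (0.11) and Cxcl9 in macrophages (0.093), KPL vehicle against KP vehicle; Ccl3 in macrophages with BGB324 (-0.052); Ifi27l2a in CD8 T cell: KPL anti-PD-1 vs KPL vehicle (-0.049), and Ccr7 (0.052) and H2-Ab1 (0.019) in dendritic cells there; Ifi27l2a in conventional CD4 T cells with the combination (0.062, and 0.0079 at 1000 UMIs); Apoe (0.0076) and Axl (0.060) in macrophages, combination against anti-PD-1; and Cxcl10 (0.059) there against BGB324.

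Clonotypes by TRB nucleotide sequence gave 14.6% in KP vehicle (8.07%), 23.7% in KPL vehicle (14.4%), 31.5% in anti-PD-1 (17.7%) and 44.3% in the combination (30.4%). Without drawing, the last 3 were 22.1%, 30.4% and 44.8%. Depth limits small differences: in CD8 T cells simulated with counting error only, 84.7% of genes changed 1.5-fold had intervals on the true side of 0.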

Other observations

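Of the tests below, the one of carried-over barcodes was chosen only after the result was seen. A TRB amino acid sequence, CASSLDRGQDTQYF with TRBV16 and TRBJ2-5, was found in all 4 TCR libraries, in 12, 12, 49 and 22 barcodes of KP vehicle, KPL vehicle, anti-PD-1 and combination, or 3.73%, 1.52%, 5.29% and 1.97% of barcodes. Conventional CD4 T cells held 10, 9, 33 and 17 of them. It was written in 22 nucleotide sequences, and 41 of 48 barcodes with a TRA chain used TRAV21-DV12. A further sequence, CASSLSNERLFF with TRBV29 and TRBJ1-4, was found in 7, 5, 8 and 19 barcodes with 6 nucleotide sequences, and CD8 T cells held 3, 5, 7 and 16. No other TRB amino acid sequence with its V and J genes besides these 2 was in all 4 libraries.

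Of the 95 barcodes with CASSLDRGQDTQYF, 0 carried it in another library under the same barcode, which argues against contigs carried over with their cell barcodes. For cells of 1 clone mixed into other libraries, the TRA chain was read too. Of barcodes with a TRA chain, 31.25% (15 of 48, interval 18.7 to 46.3) had TRA and TRB nucleotide sequences both found in another library. Other barcodes had 0.666% (11 of 1652). The sequence was picked for lying in all 4 libraries, so this comparison does not bear on mixing. The 31.25% lies between what mixing of most cells and what no mixing would give. Separate mice can make the same short rearrangement, so mixing stays open. The 22 nucleotide sequences are more than 1 clone can carry, so 1 clone alone is not the whole source.

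A gamma-delta sub-cluster, with Trdc and Cd163l1, held 11.1% of T cells in KP vehicle, 8.01% in KPL vehicle, 2.54% in BGB324, 5.04% in anti-PD-1 and 4.18% in the combination. Neutrophils of cluster 1, led by Stfa2l1, Fpr1, S100a8 and S100a9, were 3.45%, 1.11%, 17.1%, 2.80% and 28.0% of neutrophils. The part of BGB324 depends on the clustering: a cluster led by S100a8, S100a9, Stfa2l1 and Fpr1 held 51 BGB324 and 1053 combination neutrophils at Leiden resolution 2, 14 and 691 at 1000 UMIs or more, and 531 and 1280 without doublet removal.

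Chtf8 was read at 39.9 CPM over all cells of the BGB324 library, and at 1.47 CPM in KPL vehicle, Bc1 was read at 32.9 CPM in KPL vehicle over all cells, and Hypk was 5.40 CPM there against 63.5 to 91.2 elsewhere. Scamp4 and Kcna3 were 20.7 and 19.7 CPM in BGB324 against 2.18 to 4.03 and 1.06 to 2.18 elsewhere, and Sap18b and Dynlt1f were 2.03 and 2.85 CPM in KPL vehicle against 6.48 to 33.3 and 12.4 to 30.2. No explanation was tested for these library-wide genes, and a different alignment of 1 library is not excluded, so their ratios with that library do not show a change in expression.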
